A study of Mus musculus with 6 samples.

How the data were processed

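Messenger RNA was profiled in MB21 cells, a mouse medulloblastoma line with a mutation in Ptch, grown without attachment in serum-free B27 medium. Per the labels' protocols, cells received the compound DS-1-38 (DS38 in the sample names) at 10 uM or its vehicle, DMSO, for 1 day. The series' design text instead names 5 days; the series title, sample titles and treatment protocol all give 1 day, which is used here. Each group had 3 libraries, made with a column RNA kit and a poly(A)-based library kit on a robot, per the labels' protocols. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

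The authors deposited 1 table of whole-number read counts per gene for the 6 libraries, with a gene length in bases. Per the submitters' processing notes, STAR 2.7.9a, featureCounts, Subread 2.0.3, R 4.1.0 and edgeR were used, with the builds GRCm39 and GRCh38.p13; the notes give them no role or order. The strand setting and the handling of reads that match several genes are not given in the sources used here. Reads of near-identical copies and of overlapping or antisense genes therefore cannot be assigned with certainty. The table had 55416 Ensembl gene identifiers, of which 23047 were 0 in every library. Symbols were matched for 52083 identifiers; the rest held 0.345% of all counts, and 85 of the tested genes had no symbol. Gene classes came from the GENCODE M21 annotation of GRCm38, an older build than that of the authors, so no coordinates are given.

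Library totals were 38840296 to 50014681 counts in DMSO and 60434089 to 84044428 in DS38, so every DS38 library was deeper than every DMSO library. A count of 0 in all libraries, taken as at most 3 counts of their summed total, allows up to 0.00831 CPM. Such limits cover counting error only.

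Computation used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 17679 genes, and libraries were scaled by TMM. DS38 was compared with DMSO by edgeR's two-sided quasi-likelihood test with group as the sole term, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.0330. Fold changes are log2 values of DS38 over DMSO with their standard errors (SE), and levels are TMM-normalized CPM as mean ± SD of 3 libraries. Within groups, log2 CPM correlated at r = 0.9932 to 0.9965 across genes. Between groups r was 0.9919 to 0.9932, and the ranges overlapped slightly. The chi-square statistic of each within-group pair was at least 2.79 times its degrees of freedom, so every pair differed by more than sampling noise. This ratio was 7.82 to 8.76 for DMSO pairs, 2.79 to 3.37 for DS38 pairs and at least 9.77 between groups.

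Before the data were examined, 36 gene lists were fixed, and the 33 with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation was run beside it, as was fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. No list passed with an estimated correlation: the lowest adjusted p was 0.123, and 8 lists had an unadjusted p under 0.05. The estimate was below the preset one for the hedgehog targets (-0.055), pro-survival regulators (-0.075) and p53 targets (-0.018). These lists also did not pass, so their loss was not due to a higher estimated correlation. With fry, 19 lists passed. In splits of the libraries that mix the groups, camera at the preset correlation still called up to 11 lists, though such splits keep part of the group difference. Genes to be named were also set by a rule beforehand. The rule took all tested hedgehog targets and members of the EYA-SIX-DACH network, and the 12 largest rises and 12 largest falls past the threshold. The latter needed at least 5 CPM in the higher group and no overlap between groups, and left out symbols of the Gm-number and Rik kind. It further took from every other list the 4 members of smallest adjusted p in each direction (the 2 of smallest p where none passed), the 2 most abundant members of each list of another cell type, and the 5 smallest p. Some of the genes so chosen are not reported here.

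Alternatives fixed beforehand were DESeq2, limma-voom, DESeq2's size factors within edgeR (RLE), library size alone, no filter on low counts, a stricter filter (5 CPM in 3 libraries), the replicate number as a block, robust dispersion, and leaving out each library in turn. Thinning to the smallest library total, corrections for gene length and for GC content, and protein-coding genes alone were added after seeing the data. The tests were tested on simulated data for DS38 against DMSO with 17679 genes. In them edgeR called 31 of 48 genes changed by 1.2-fold, 32 of 49 by 1.5-fold, 45 of 49 by 2-fold and 44 of 48 by 3-fold, and 11 of 17213 unchanged genes. A simulated list shifted by -0.2 on the log2 scale had a camera adjusted p of 0.00250 with an estimated correlation. No unshifted list was called with the preset one. Genes were simulated as independent, whereas the estimated correlation in the real lists reached 0.81, for the mitochondrial genome. The simulation therefore cannot show how either form of camera behaves with correlated genes. The length correction brought a simulated slope of -0.10 per doubling of length to -0.0035.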

Results

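Gene expression was measured by RNA sequencing in 6 libraries of MB21 cells, 3 treated with DMSO and 3 with DS38, a derivative of benzarone, for 1 day at 10 uM. MB21 is a mouse medulloblastoma line with mutant Ptch, the receptor that restrains hedgehog signalling. The comparison addresses how a compound intended against hedgehog-driven medulloblastoma alters expression in such cells. Benzarone is known as an inhibitor of the tyrosine phosphatase activity of EYA proteins. Totals were 50014681, 48560824 and 38840296 counts in DMSO replicates 1 to 3, and 79254309, 60434089 and 84044428 in DS38 replicates 1 to 3. The first principal component held 37.8% of the variance and separated the groups, and the second, with 22.2%, set DMSO replicate 3 apart.

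After 1 day of DS38, 26 of 31 integrated stress response genes, 19 of 31 autophagy and lysosome genes and 11 of 22 fatty acid oxidation genes rose. In turn, 20 of 25 sterol synthesis genes, 28 of 40 DNA replication genes and 6 of 11 hedgehog targets fell. Each of these lists passed camera at the preset correlation, and none passed with an estimated one (lowest adjusted p = 0.123 with an estimated correlation). Trim66, a tripartite-motif protein, rose from 6.96 ± 0.792 to 21.5 ± 1.77 CPM (SD, n = 3), a log2 fold change of 1.62 ± 0.077 (SE; edgeR adjusted p = 5.556e-12). Fat2, a giant cadherin of cerebellar granule cells, fell from 82.7 ± 9.51 to 34.4 ± 0.784 CPM (log2 fold change -1.27 ± 0.055; edgeR adjusted p = 2.355e-12). Of 17679 genes tested, edgeR called 4340 (24.5%), 2272 higher and 2068 lower in DS38, with a median absolute log2 fold change of 0.21. Among the calls, 77 genes were higher and 110 lower by 2-fold or more. These counts were 26 and 30 with DESeq2, 3 and 7 with the stricter filter, and 106 and 205 without DMSO replicate 3. Without a filter on low counts 187 were lower by 2-fold or more, and among protein-coding genes alone, 25. The share of calls that were higher, 52.4%, depended on scaling: with library size alone, 3289 genes were higher and 1543 lower (68.1% higher). In 6824 tested genes (38.6%), the groups did not overlap, against 10% by chance, and 4108 of the called genes were among them. Of the called genes that were still tested, 20 changed sign with the length correction, 2 with the GC correction and 1 without DMSO replicate 3.

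Among the largest rises were Calb2 (calretinin), P2rx3 (an ATP-gated ion channel) and Prph (peripherin, an intermediate filament of neurons). A lack of overlap between groups was a condition for naming these rises and the large falls below. Calb2 went from 4.67 ± 0.345 to 13.1 ± 0.338 CPM (SD, n = 3) and P2rx3 from 2.02 ± 0.229 to 5.56 ± 0.494. Prph rose by 0.94 ± 0.091 on the log2 scale (SE). Cabp1, Fuca2 and Cyb5r1 rose by 0.89 ± 0.075, 0.87 ± 0.076 and 0.87 ± 0.046. Large falls included Nos1 (neuronal nitric oxide synthase, log2 fold change -1.03 ± 0.10), Rag1 (-1.16 ± 0.12) and Sema3e (a secreted axon guidance factor, -0.86 ± 0.089). Cdhr1, the presynaptic scaffold gene Pclo and Pld1 fell by 0.80 ± 0.058, 0.79 ± 0.071 and 0.78 ± 0.051. Kcnq1ot1, a non-coding RNA antisense to Kcnq1, had a log2 fold change of -0.86 ± 0.083, but its reads cannot be told from those of its partner where strand was not counted. Serpinb6e (-1.54 ± 0.14) and Vmn2r-ps94 (-1.36 ± 0.13) belong to families of near-identical copies and are uncertain. ENSMUSG00000119584, which has no symbol here, was at 4559 ± 2362 CPM in DMSO and 2212 ± 239 in DS38, and its call was lost with robust dispersion (edgeR adjusted p = 0.169) and DESeq2 (adjusted p = 0.0656).

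**Figure D1:**
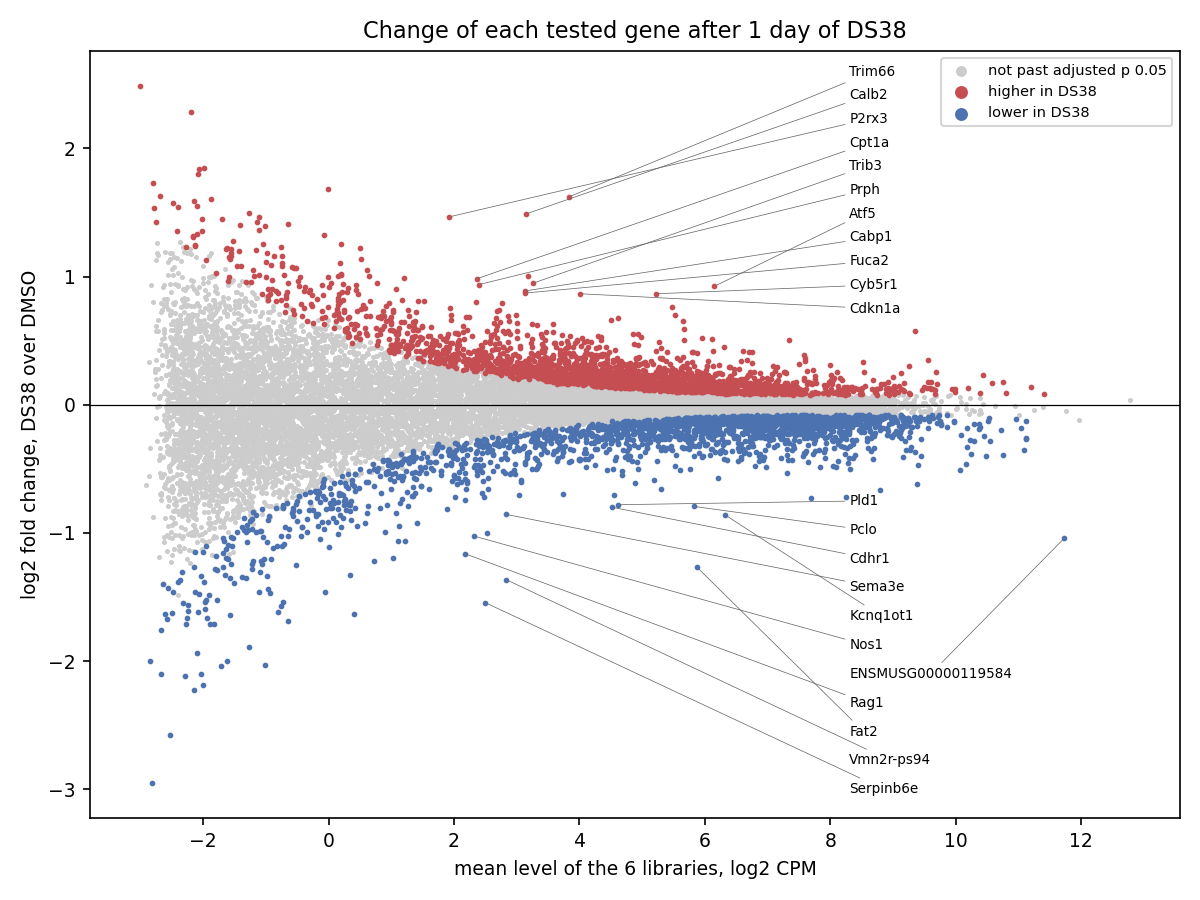
Log2 fold change of DS38 over DMSO (vertical axis) against the mean level of the 6 libraries in log2 CPM (horizontal axis), 1 point per tested gene. Red and blue points are the 2272 higher and 2068 lower genes past adjusted p 0.05, grey points the others, and the names mark genes among the 12 largest rises and 12 largest falls chosen by the rule.

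Hedgehog targets were lower in DS38. Of 11 tested members 1 rose and 6 fell, and the counts adjusted over the list alone were also 1 and 6 (camera adjusted p = 3.647e-04; adjusted p = 0.123 with an estimated correlation). Sox18 fell from 140 ± 4.85 to 105 ± 1.90 CPM (SD, n = 3), and Hhip, a hedgehog-binding antagonist that the pathway induces, from 86.7 ± 2.62 to 67.8 ± 2.35. Ptch1 fell by 0.19 ± 0.030 and Gli1, the transcriptional effector most used as a readout of the pathway, by 0.15 ± 0.035 on the log2 scale (SE; edgeR adjusted p = 6.410e-05 and 0.00369). Ccnd1, which encodes cyclin D1, fell by 0.13 ± 0.027, whereas Ccnd2, cyclin D2, rose by 0.19 ± 0.029. Mycn (log2 fold change -0.004 ± 0.036), Sfrp1 (0.02 ± 0.027), Rab34 (-0.04 ± 0.060) and Foxf1 (-0.07 ± 0.33, at 0.361 CPM in DMSO) did not pass. Igf2, Nkx2-2, Foxl1 and Spp1 had 2, 6, 0 and 24 counts in all libraries together and were not tested; without a filter on low counts, the mean of the list turned from -0.12 to 0.12, while its median was -0.09. Among pathway components, Gli2, Gas1 and Evc fell by 0.16 ± 0.034, 0.15 ± 0.033 and 0.19 ± 0.037, and 3 rose and 6 fell of 17 tested. Adjusted over the list alone, 3 rose and 8 fell; that list did not pass (camera adjusted p = 0.342), and its mean of 0.03 differs in sign from its median of -0.03.

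**Figure D2:**
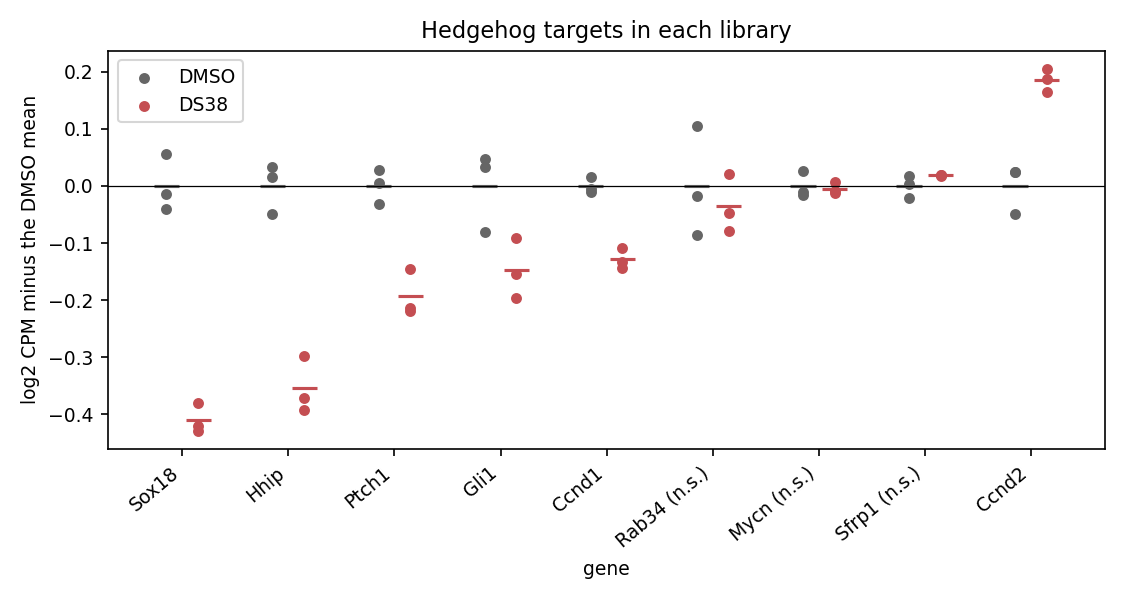
Log2 CPM of each library minus the DMSO mean (vertical axis) for hedgehog targets named in the text with at least 5 CPM in DMSO (horizontal axis), which leaves out Foxf1. Points are libraries, short lines are group means, and n.s. marks genes that did not pass adjusted p 0.05; for each plotted gene that fell, all 3 DS38 libraries lie below all 3 DMSO libraries.

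Of the EYA proteins, which the parent compound is known to inhibit, Eya3 was the main member measured, at 100.2 ± 1.15 CPM in DMSO and 100.5 ± 2.16 in DS38 (SD, n = 3), and did not pass (log2 fold change 0.004 ± 0.030; edgeR adjusted p = 0.941). Eya4 was at 2.00 ± 0.317 and 2.58 ± 0.0993 CPM (edgeR adjusted p = 0.0627). Eya1 had 0 counts in all 6 libraries, which allows up to 0.00831 CPM in counted reads and leaves open whether the gene was silent or lost in counting. Eya2, Six6 and Dach2 had 32, 0 and 23 counts in total. Dach1, a transcriptional cofactor that acts with EYA proteins, rose from 12.7 ± 0.474 to 15.4 ± 0.820 CPM (edgeR adjusted p = 0.00143). Six5, Six4 and Six3 had log2 fold changes of 0.15 ± 0.062, 0.54 ± 0.20 and 0.97 ± 0.39, and Six2 of -0.01 ± 0.11; none passed. Of 7 tested members of the EYA-SIX-DACH network 1 rose, or 5 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0818). It passed with fry (adjusted p = 0.00218) and without a filter on low counts (adjusted p = 0.0233), and 4 members rose with library size alone and 3 with the length or GC correction.

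Genes of the integrated stress response, the program that follows phosphorylation of the translation factor eIF2alpha, were higher. Of 31 tested members 26 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 0.18 (camera adjusted p = 1.472e-23; adjusted p = 0.123 with an estimated correlation). Atf5, a transcription factor of this response, rose from 48.9 ± 4.19 to 92.9 ± 0.663 CPM (SD, n = 3; edgeR adjusted p = 5.268e-12). Trib3, a pseudokinase, rose by 0.95 ± 0.083, Cth, an enzyme of cysteine synthesis, by 0.68 ± 0.052, and Aldh1l2, a mitochondrial folate enzyme, by 0.41 ± 0.034 on the log2 scale (SE). In the unfolded protein response list, Xbp1 rose by 0.28 ± 0.049 and Herpud1 by 0.20 ± 0.037, Dnajc3 fell by 0.16 ± 0.030, and 2 rose and 2 fell of 22, also adjusted over the list alone (camera adjusted p = 0.639). Of that list 4 rose without DMSO replicate 3 or with limma-voom, and 5 with library size alone. The number that fell was 1 with library size alone and without DS38 replicate 1 or 3.

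Targets of the oxidative-stress factor NRF2 were higher. Of 22 members 11 rose and 3 fell, or 13 and 3 adjusted over the list alone (camera adjusted p = 5.601e-06; adjusted p = 0.189 with an estimated correlation). Hmox1, heme oxygenase, rose from 11.8 ± 0.435 to 17.1 ± 0.450 CPM, Gstm1 from 25.8 ± 0.814 to 37.2 ± 0.439, and the ferritin genes Ftl1 and Fth1 by 0.39 ± 0.032 and 0.26 ± 0.028 on the log2 scale. The members that fell were Pgd, Tkt and Txnrd1, and none of the 3 passed without DS38 replicate 3 (edgeR adjusted p = 0.0520, 0.115 and 0.128). A single NRF2 target fell without DS38 replicate 2 or with library size alone, and 5 with the length correction. Autophagy and lysosome genes were higher. Of 31 members 19 rose and 0 fell, or 20 and 0 adjusted over the list alone (camera adjusted p = 8.162e-10; adjusted p = 0.123 with an estimated correlation). Among those that rose were Sqstm1, an autophagy receptor (121.6 ± 3.93 to 150.02 ± 3.53 CPM), the protease gene Ctsl (log2 fold change 0.25 ± 0.031), Psap (0.21 ± 0.029) and Wipi1 (0.39 ± 0.057). In the xenobiotic response list, 3 of 7 rose, also adjusted over the list alone, where 1 fell (camera adjusted p = 0.549). The number that rose was 0 without DS38 replicate 3 and 1 with DESeq2, thinning, or any of DMSO replicates 1 and 2 and DS38 replicates 1 and 2 left out.

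Sterol synthesis genes were lower. Of 25 members 0 rose and 20 fell, also adjusted over the list alone, with a median of -0.27 (camera adjusted p = 1.874e-29; adjusted p = 0.123 with an estimated correlation). Cyp51, lanosterol demethylase, fell from 375 ± 8.57 to 281 ± 4.53 CPM (SD, n = 3), and Idi1, an enzyme of the same route, fell by 0.47 ± 0.039 on the log2 scale. Fatty acid synthesis genes were lower as a list. Of 16 members 3 rose (Gpam, Me1 and Acss2) and 8 fell, or 3 and 9 adjusted over the list alone (camera adjusted p = 1.407e-07; adjusted p = 0.189 with an estimated correlation). Fasn, fatty acid synthase, fell from 780 ± 43.9 to 564 ± 12.9 CPM, and Scd2, Elovl6 and Acaca fell by 0.33 ± 0.028, 0.38 ± 0.029 and 0.35 ± 0.031. Fatty acid oxidation and PPAR genes were higher. Of 22 members 11 rose and 0 fell, or 15 and 0 adjusted over the list alone (camera adjusted p = 5.065e-06; adjusted p = 0.142 with an estimated correlation). Cpt1a, which admits long-chain fatty acids to mitochondria, rose from 3.45 ± 0.507 to 6.81 ± 0.514 CPM, and Decr1, Acot2 and Hadh rose by 0.51 ± 0.099, 0.48 ± 0.092 and 0.22 ± 0.034.

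DNA replication and G1/S genes were lower. Of 40 members 0 rose and 28 fell, or 1 and 29 adjusted over the list alone (camera adjusted p = 6.882e-13; adjusted p = 0.123 with an estimated correlation). Ccne2, cyclin E2, fell from 90.5 ± 2.07 to 67.6 ± 1.94 CPM, and Tyms (thymidylate synthase), E2f8 and the helicase subunit gene Mcm4 fell by 0.30 ± 0.034, 0.27 ± 0.032 and 0.22 ± 0.027 on the log2 scale. The mitosis list did not pass (camera adjusted p = 0.342), with 2 members higher and 5 lower of 40, also adjusted over the list alone. Within it Pttg1 and Ccnb2 rose by 0.34 ± 0.062 and 0.16 ± 0.036, while Mki67 fell from 1373 ± 137 to 1053 ± 38.1 CPM and Cenpf and Top2a fell by 0.34 ± 0.046 and 0.13 ± 0.029. With a correction for gene length, chosen after seeing the data, that list passed (adjusted p = 0.0282), and 12 members fell. The number that rose was 4 without DMSO replicate 3 and 7 with library size alone. DNA damage repair genes were lower. Of 35 members 1 rose and 15 fell, or 2 and 16 adjusted over the list alone (camera adjusted p = 5.065e-06; adjusted p = 0.189 with an estimated correlation). Clspn, Atm and Fancm fell by 0.28 ± 0.028, 0.43 ± 0.046 and 0.40 ± 0.045, and Xrcc5 rose by 0.18 ± 0.032.

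Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose from 11.5 ± 0.659 to 20.8 ± 1.38 CPM (SD, n = 3; edgeR adjusted p = 3.439e-09). Sesn2, which is also in the integrated stress response list, rose by 0.41 ± 0.038 and Fdxr by 0.29 ± 0.058, whereas Btg2 fell by 0.22 ± 0.028 on the log2 scale. Of 28 p53 targets 7 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0493; adjusted p = 0.189 with an estimated correlation). That call was lost with RLE scaling (adjusted p = 0.0511), the stricter filter (0.147), thinning (0.0641), protein-coding genes alone (0.153), the length (0.168) and GC (0.0509) corrections, and without DMSO replicate 1 (0.0676), DMSO replicate 3 (0.0807) or DS38 replicate 1 (0.0607). Pro-survival regulators of apoptosis were lower. Of 9 members 1 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.00702; adjusted p = 0.169 with an estimated correlation). Without DMSO replicate 2 the number that fell was 3, and 0 rose without DMSO replicate 2, DS38 replicate 1 or DS38 replicate 3. Without a filter on low counts, the mean of the list turned from -0.13 to 0.05. Bcl2 fell from 30.5 ± 1.39 to 23.7 ± 0.404 CPM and Birc6 and Bcl2l1 by 0.45 ± 0.054 and 0.16 ± 0.035. The pro-death list did not pass (camera adjusted p = 0.837); 3 rose and 3 fell of 17, also adjusted over the list alone, with Casp9 up by 0.20 ± 0.048. Without DS38 replicate 2 or 3, or with library size alone, 1 of that list fell, and after thinning 1 rose.

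Of 40 ribosomal protein genes 23 rose and 0 fell, or 26 and 0 adjusted over the list alone. That list passed with camera (adjusted p = 9.703e-07; adjusted p = 0.517 with an estimated correlation) but not with fry (adjusted p = 0.0633). Rps14 rose from 511 ± 28.8 to 607 ± 18.2 CPM and Rplp0 by 0.17 ± 0.032 on the log2 scale. Ribosome biogenesis and MYC genes were lower. Of 35 members 1 rose and 14 fell, or 1 and 17 adjusted over the list alone (camera adjusted p = 1.663e-05; adjusted p = 0.189 with an estimated correlation). Utp20, a component of ribosomal RNA processing, fell by 0.43 ± 0.035, Polr1a, the largest subunit of RNA polymerase I, by 0.24 ± 0.029 and the nucleolar gene Ncl by 0.20 ± 0.029, and Odc1 rose by 0.26 ± 0.028. Genes of the mitochondrial genome were lower, mt-Nd2 at 1257 ± 281 CPM in DMSO and 884 ± 50.3 in DS38. DMSO replicate 3 lay within the DS38 range for others of them: mt-Nd1 was at 1549.8 CPM there, against 1421.7 to 1550.2 in DS38, and 2352.5 and 1994.8 in the other DMSO libraries. Of 13 tested 0 rose and 12 fell, also adjusted over the list alone (camera adjusted p = 1.721e-06; adjusted p = 0.363 with an estimated correlation; fry adjusted p = 0.162). With DESeq2 2 of them fell, with robust dispersion 1, and without DMSO replicate 1 8.

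Heat shock genes were lower as a list. Of 17 members 1 rose and 7 fell, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.0234; adjusted p = 0.384 with an estimated correlation). Hsph1, a co-chaperone, fell from 661 ± 15.99 to 557 ± 10.4 CPM, Dnaja1 and Hsp90aa1 fell by 0.18 ± 0.027 and 0.13 ± 0.028 on the log2 scale, and the small heat shock gene Cryab rose by 0.73 ± 0.14. The median was -0.08 and the mean -0.002. The mean turned above 0 with library size alone (0.03), the replicate block (1.008e-04), and without DMSO replicate 3 (0.02) or DS38 replicate 3 (0.03). The call was lost with library size alone (adjusted p = 0.0516) and without DS38 replicate 3 (0.0871). The number that fell was 4 without DS38 replicate 2 and 12 with the length correction. NOTCH targets were higher, and 3 of 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0457; adjusted p = 0.238 with an estimated correlation). Dtx1 rose from 69.3 ± 1.49 to 82.1 ± 1.70 CPM. That call was lost with library size alone (adjusted p = 0.0551), the replicate block (0.0536), the length (0.0706) and GC (0.111) corrections, protein-coding genes alone (0.0810), and without DMSO replicate 1 (0.0517) or DS38 replicate 1 (0.0593).

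Genes of the granule cell lineage, from which this tumour class arises, went both ways. Atoh1, the transcription factor of granule progenitors, rose from 327 ± 8.37 to 411 ± 5.49 CPM and Barhl1 by 0.27 ± 0.030, while Zic4, Nhlh1 and Zic5 fell by 0.32 ± 0.030, 0.22 ± 0.029 and 0.20 ± 0.032 on the log2 scale. Of 16 members 4 rose and 5 fell, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.646). Among neuronal differentiation genes Neurod1 fell from 113 ± 3.37 to 87.4 ± 4.40 CPM, and Elavl3, Dcx and Gap43 fell by 0.28 ± 0.029, 0.26 ± 0.032 and 0.23 ± 0.029, while Calb2, Snap25 (0.32 ± 0.058) and Syt1 (0.29 ± 0.060) rose. In that list 4 rose and 12 fell of 23, also adjusted over the list alone, with a camera adjusted p of 0.0516 that ranged from 0.0137 to 0.111 over the alternatives at the preset correlation. It passed with RLE scaling (adjusted p = 0.0497), no filter on low counts (0.0470), thinning (0.0349), the GC correction (0.0137), protein-coding genes alone (0.0399) and fry (0.0327). It also passed without DMSO replicate 2 (adjusted p = 0.0306), DMSO replicate 3 (0.0216) or DS38 replicate 2 (0.0472). Nes, the intermediate filament nestin of neural progenitors, fell from 803 ± 28.8 to 525 ± 22.0 CPM (edgeR adjusted p = 2.676e-11), Sox9 and Sox2 fell by 0.18 ± 0.031 and 0.23 ± 0.056, and Cd44 rose by 0.25 ± 0.038. Of 13 neural stem markers 2 rose and 4 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.140). The list passed with the GC correction (0.0499) and fry (0.0206), and 1 member rose without DMSO replicate 2, DS38 replicate 1 or DS38 replicate 2.

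**Figure D3:**
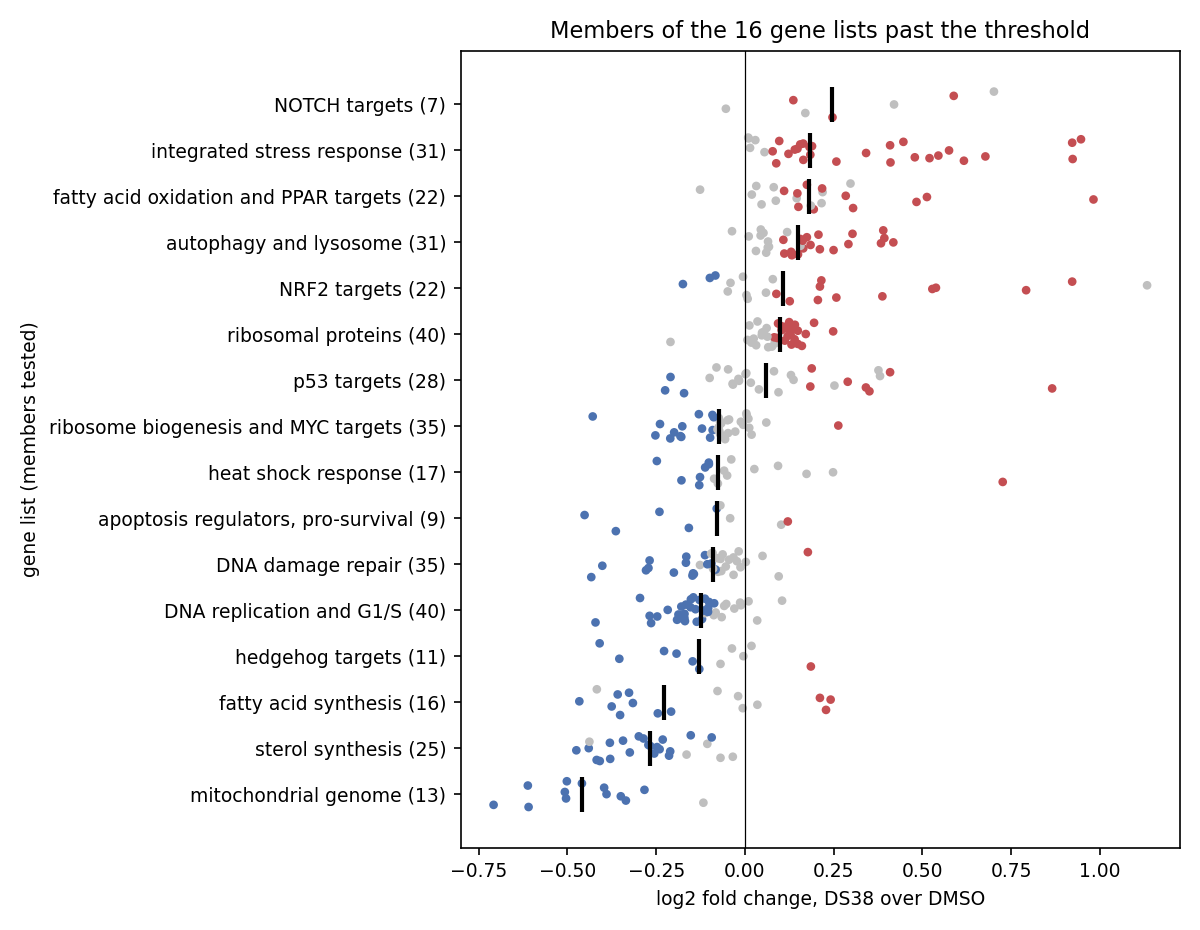
Log2 fold change of DS38 over DMSO (horizontal axis) of every tested member of the 16 lists past camera adjusted p 0.05 (vertical axis, tested members in brackets). Red points rose and blue points fell past adjusted p 0.05, grey points did not pass, and black bars are medians, from -0.46 for the mitochondrial genome to 0.25 for NOTCH targets.

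Markers of other cell types were low or did not pass as lists with camera. Cd68 of macrophages was at 1.46 ± 0.235 CPM in DMSO and 1.61 ± 0.271 in DS38, Lum of fibroblasts at 0.716 ± 0.0782 and 1.09 ± 0.237, and Pecam1 of endothelium at 0.448 ± 0.260 and 0.531 ± 0.00628; none of the 3 passed. Col1a1 rose from 0.373 ± 0.168 to 0.822 ± 0.258 CPM, a call lost without DMSO replicate 2 (edgeR adjusted p = 0.0887) or DS38 replicate 1 (0.0980). The microglia, fibroblast and endothelial lists had 2, 4 and 4 tested members and no list test. The astrocyte transporter gene Slc1a2 fell from 309 ± 11.4 to 249 ± 3.86 CPM, while Slc1a3 was at 144 ± 4.29 and 139 ± 3.18 and did not pass. Of 6 astrocyte markers 1 rose and 1 fell (camera adjusted p = 0.483), and of 9 oligodendrocyte markers 1 rose, Olig1 (camera adjusted p = 0.636; fry adjusted p = 0.0317), counts that were the same adjusted over the lists alone. No astrocyte marker rose without DMSO replicate 1 or DS38 replicate 2, and no oligodendrocyte marker rose without DS38 replicate 2.

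The remaining lists did not pass with camera. Glycolysis and hypoxia genes were mixed, with Hk1 and Vegfa up by 0.28 ± 0.038 and 0.23 ± 0.038 and Hk2 and Pfkfb3 down by 0.23 ± 0.029 and 0.46 ± 0.072 on the log2 scale; 11 rose and 5 fell of 33, or 12 and 7 adjusted over the list alone (camera adjusted p = 0.636). Of these, 5 rose without DS38 replicate 1, and 7 without DMSO replicate 1, DMSO replicate 2 or DS38 replicate 3. With the length correction 6 rose and 9 fell, and with the GC correction 8 and 9. Nuclear oxidative phosphorylation genes numbered 4 higher and 3 lower of 40, also adjusted over the list alone (camera adjusted p = 0.505), with Uqcrc2 up by 0.13 ± 0.030; without DMSO replicate 3, 14 rose and the list passed (adjusted p = 0.0364). With library size alone 12 of them rose and 1 fell; 2 rose without DMSO replicate 1 or DS38 replicate 1, and 1 and 0 fell without DS38 replicates 2 and 3. Immediate early genes, with Atf3 up by 0.62 ± 0.099 and Dusp6 and Dusp4 down by 0.26 ± 0.041 and 0.30 ± 0.051, had 6 higher and 5 lower of 23, also adjusted over the list alone (camera adjusted p = 0.783). Atf3 is also in the integrated stress response list. Interferon genes had 4 higher and 3 lower of 21, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.837), with B2m up by 0.20 ± 0.030 and Ifih1 down by 0.30 ± 0.053; 2 rose without DMSO replicate 1, DMSO replicate 2, DS38 replicate 1 or DS38 replicate 3. In the BMP and TGF-beta list 3 rose and 0 fell of 9, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.164; fry adjusted p = 0.0345), with Skil up by 0.20 ± 0.035. Of 9 WNT targets Znrf3 fell, by 0.19 ± 0.035, also adjusted over the list alone (camera adjusted p = 0.887). For the WNT, astrocyte and immediate early lists, the direction of the test (lower) differed in sign from the mean (0.10, 0.03 and 0.003).

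Transcript length and RNA class differed between the libraries as well. Across 10231 protein-coding genes, the log2 fold change fell with gene length (Spearman rho = -0.22 across genes, which are not independent replicates), and the longest of 10 equal bins had a median of -0.07 against 0.03 in the shortest. The slope of each library on log2 length was 0.036, 0.025 and -0.013 in DMSO and -0.019, -0.021 and -0.0088 in DS38, so DMSO replicate 3 lay within the DS38 range (exact permutation p = 0.2, two-sided, n = 3). Loci of the TEC class, annotated as awaiting experimental evidence, numbered 6 higher and 113 lower of 629, and were 49 of the 110 genes lower by 2-fold or more. Processed pseudogenes, whose reads may belong to near-identical copies, numbered 18 higher and 160 lower of 1970, with a median log2 fold change of -0.15 against -0.28 for TEC loci and 0.02 for protein-coding genes. The share of TEC loci that fell, 17.97%, exceeded the 12.7% of protein-coding genes (odds ratio 1.501, 95% interval 1.21 to 1.86, Fisher's exact p = 2.559e-04), across genes, which are not independent replicates. The median log2 level of these loci, less the mean of libraries, was 0.17, 0.27 and 0.019 in DMSO and -0.17, -0.099 and -0.077 in DS38 (exact permutation p = 0.1, two-sided, n = 3). Genes of the mitochondrial genome took 1.70, 1.44 and 1.09% of counts in DMSO and 1.204, 1.08 and 1.21% in DS38 (exact permutation p = 0.3, two-sided, n = 3). With 3 libraries against 3, the smallest p such a test allows is 0.1. Long genes named above as falls include Fat2 and Birc6, at 14528 and 25772 bases, and Atm, Mki67 and Cenpf, at 10338, 10061 and 15433 bases.

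**Figure D4:**
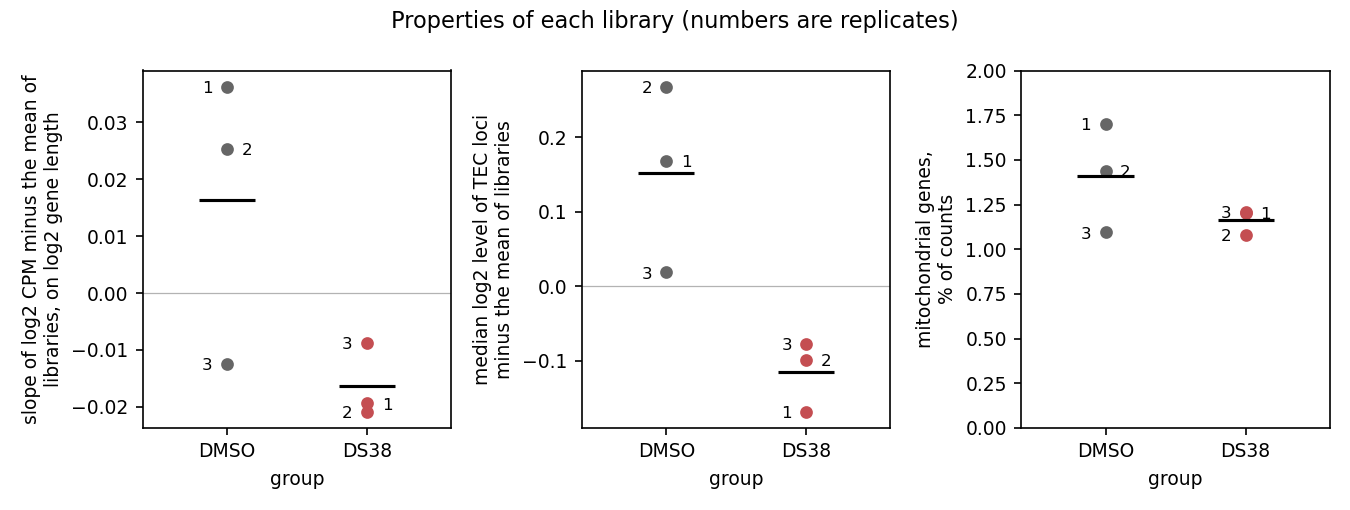
Slope of log2 CPM (minus the mean of libraries) on log2 gene length, median log2 level of TEC loci minus the mean of libraries, and share of counts from mitochondrial genes in percent (vertical axes), by group (horizontal axis). Points are libraries numbered by replicate and lines are group means; DMSO replicate 3 lies among or nearest to the DS38 libraries in all 3 panels.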

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

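The thinned, length-corrected, GC-corrected and protein-coding settings were chosen only after seeing the data. Over all alternatives no named gene past the threshold changed sign and no list past it changed camera's direction. The mean of the hedgehog list did turn from -0.12 to 0.12, and that of the pro-survival list from -0.13 to 0.05, without a filter on low counts. Counts of all higher and all lower genes moved by less than 1.5 times in every setting, from 1640 to 2437 and from 1549 to 2474 with 1 library left out. The counts of 2-fold changes depended on the filter and tool. DESeq2, whose own filter left 14797 genes with an adjusted p, gave 26 higher and 30 lower, and the stricter filter, which leaves 10604 genes, 3 and 7. Without a filter 187 genes were lower, and among protein-coding genes 25. Leaving out 1 library gave 81 to 205 lower by 2-fold, the highest without DMSO replicate 3; the cause was not tested. With an estimated correlation 0 lists passed in either direction, against 7 and 9, and the hedgehog targets had adjusted p = 0.123. At the preset correlation the hedgehog list passed in every alternative run, from 9.837e-05 without DMSO replicate 1 to 0.00111 without DS38 replicate 1 when libraries were left out. Of 185 calls among the named genes, 40 were lost in at least 1 alternative. For named genes, 3482 values held their side of the threshold, 14 came to pass it and 146 no longer did; for single lists these numbers were 502, 17 and 36. No sign was seen that the replicate numbers pair the libraries, though so few libraries cannot exclude it. Same-numbered deviations correlated at 0.035, -0.011 and -0.027, and not every library correlated best with its own number. With the replicate block, 2108 genes were higher and 1902 lower, 72 and 97 by 2-fold or more, and the NOTCH list had adjusted p = 0.0536. Every DS38 library was deeper than every DMSO library, which limits the precision of low genes in DMSO.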

Other observations

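The families of genes below, the thinned and length-corrected settings, and the test of variation between libraries in the length trend were chosen only after the data had been seen. Among 209 families sharing the start of a symbol (or, for aminoacyl-tRNA synthetases, a function), 10 passed camera at the preset correlation and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. Aldehyde dehydrogenases were higher, 8 of 14 rising and 0 falling (camera adjusted p = 1.317e-05; adjusted p = 0.714 with an estimated correlation). Aldh6a1, chosen after its values were seen, rose from 32.0 ± 0.866 to 45.0 ± 1.198 CPM (SD, n = 3). Tetraspanins rose in 10 of 16 members (camera adjusted p = 4.057e-05; adjusted p = 0.714 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, rose in 10 of 18 (camera adjusted p = 0.0298; adjusted p = 0.919 with an estimated correlation). Kmt genes, mostly histone methyltransferases, fell in 6 of 8 and rose in 1 (camera adjusted p = 0.00311; adjusted p = 0.919 with an estimated correlation). Kmt2a, Kmt2d and Kmt2c, chosen after their values were seen, fell by 0.48 ± 0.056, 0.35 ± 0.043 and 0.34 ± 0.049 on the log2 scale (SE), with gene lengths of 16670, 19931 and 20291 bases. Sox transcription factors fell in 6 of 13 and rose in 1 (camera adjusted p = 0.0364; adjusted p = 0.919 with an estimated correlation).

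The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of them, the real one, edgeR called as many as 4340 genes, against at most 0 in the others (209 to 911 genes at an unadjusted p under 0.05; at most 0 calls with limma-voom and 3 with DESeq2). For changes of 2-fold or more, 1 split, the real one, gave 187, and the highest other gave 0. For gene lists 1 split, the real one, gave 16, and the highest other gave 11, so that camera at the preset correlation also called lists in splits that mix the groups. Each side of such a split holds both groups in unequal numbers. It therefore keeps part of the group difference, which also adds to the spread within its sides. Neither the list calls nor the gene calls of these splits are free of a group effect.

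Integrated stress response genes were higher in DS38. Greater depth of the DS38 libraries was predicted to leave under 13 of the 26 members past the threshold after thinning, and 25 passed. Thinning keeps the expected fold changes of well-counted genes. It shows that these calls did not need the extra reads. It cannot decide on other differences between libraries that go with depth. A trend with gene length was predicted to leave under 13 under the length correction, and 23 passed. The highest median of any length bin was 0.04, against 0.18 for the list, so that correction had little room to remove calls. Leaving out any 1 library left at least 23. The bin medians and the fits without 1 library argue against gene length and a single library as the whole cause. A response of the cells to DS38 may account for the pattern, as a hypothesis found and tested on the same data. Other differences between libraries that go with depth, and an unrecorded batch that follows the groups, stay open.

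Hedgehog targets were lower, with a mean log2 fold change of -0.124 and an SE of 0.051 over members. This SE and those of the shifts below are over genes of the same libraries, which are not independent replicates. The mean was -0.138 after the length correction (a shift of -0.015 ± 0.011) and -0.128 after thinning (a shift of -0.0045 ± 0.0077). Either explanation had been set to need a rise above -0.05. Thinning keeps the expected fold changes of well-counted genes. The fall did not need the unequal totals, but thinning cannot decide on other differences between libraries that go with depth. The length correction shows only that the average trend with length did not account for the fall. Of 10000 random lists matched on expression and length, 1.22% had a mean as low, which argues against a fall shared by all genes of like length and level. Pathway output was measured only through these genes, and Mycn at a log2 fold change of -0.004 and the rise of Ccnd2 run against a uniform change. Such differences, a response of the cells to DS38 and an unrecorded batch that follows the groups all stay open.

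Longer genes were lower in DS38, a trend across 10231 protein-coding genes. Depth was predicted to bring the correlation with length near 0 after thinning to equal totals, and it was -0.216. Random thinning keeps the expected fold changes of well-counted genes. The trend did not need the unequal totals, but this test cannot decide on other differences that go with depth. Variation between libraries unrelated to the compound was predicted to place at least 1 DMSO library inside the DS38 range of slopes. DMSO replicate 3 was there, but its place had been seen before the test was set and so decides nothing. Such variation can also separate the groups by chance, so a lack of overlap would not have excluded it. Other differences that go with depth, variation between libraries and an effect of DS38 on long transcripts therefore all stay open. Fat2, picked from the same data as the gene of smallest p, fell by 1.18 ± 0.044 after the length correction. The longest bin had a median of -0.07, so the average trend was too small to remove this fall.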
